A study of Mus musculus with 4 samples.

How the data were processed

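RNA was measured in 4 libraries of mouse (Mus musculus) cavernous endothelial cells, the cells that line the blood spaces of the erectile tissue, grown from corpus cavernosum tissue. Per the labels' protocols, the cells grew in medium 199 with 20% fetal bovine serum, 1% penicillin and streptomycin and 0.5 mg/ml heparin, and received glucose for 72 hours. RNA was taken with Trizol, and 1.3 µg of total RNA entered each library, made with a SMARTer mRNA sequencing kit. The labels give 2 libraries in normal glucose (replicates 1 and 2) and 2 in high glucose (replicates 2 and 4). They state neither the glucose concentrations nor an osmotic control, and they do not say that the replicates came from separate cultures or animals. The p-values below therefore measure only the spread between these libraries, which may be technical.

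The deposited files hold whole-number counts per gene symbol, 1 file per library. The submitters' processing notes name TopHat, edgeR and the mouse build mm10, without versions or roles. The counting tool, its annotation, its use of strand and its treatment of reads that match several places are not given in the sources used here. Each file has 23282 rows and 23238 symbols. Rows that share a symbol (35 symbols) were summed. Total counts were 68400019 and 46571770 in normal glucose replicates 1 and 2, and 64080301 and 74971589 in high glucose replicates 2 and 4. No library was a copy of another: the chi-square statistic per degree of freedom between pairs, against sampling noise, ran from 62.8 to 156.0. This does not show that the libraries came from separate cultures, and each was used as the replicate its label states.

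Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), using TMM scaling, the filterByExpr filter and a model with the group as its only term, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all 16270 genes tested, with a threshold of 0.05. Values are counts scaled to library size in the standard CPM unit, after TMM, given as mean ± SD with n = 2 per group unless a library is named. Log2 fold changes are high against normal glucose, from the fitted model, with standard errors (SE). The common biological coefficient of variation was 20.0%, and the prior degrees of freedom were 6.37. Intervals and floors of counts cover counting error only. A count of 0 was read against a floor of 3 counts per library.

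The design and 36 gene lists (pathways and cell type markers, 653 genes) were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, and adjusted over the 36 lists. Each list was also tested with a correlation estimated from the data and with fry. With an estimated correlation, camera takes its degrees of freedom from the libraries. These are few with 4 libraries, so a call can be lost there whatever the correlation within the list. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone.

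Genes were named by a rule fixed beforehand. It took the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 5 CPM and no overlap between groups. Open places went to the genes with the smallest unadjusted p under the same limits. It added the 5 genes with the smallest p in each direction, up to 4 members of each list with the smallest p, and Pecam1, Cdh5, Kdr, Vwf, Nos3, Txnip and Slc2a1 whatever their result. Unnamed gene models, pseudogenes and members of families with near-identical copies were passed over among the largest changes and smallest p, but not among list members, whose shared sequence is given where a value is named. Near-identical was taken as at least 10% of a gene's 32-base stretches shared with another gene. This limit was set after the data were seen, when a looser one would have let Hist1h4d through. H2-Q10, Hist1h4d, their neighbours and the members of lists chosen later were named after their values were seen. So were further members of the fixed lists, such as Hmox1, Me1, Gclm, Gsta4, Prdx1, Srxn1, Vegfa, Hif1a, Tnf, Nfkbia, Col3a1, Lox, Hgf, Cd34, Eng, Prrx1 and Pdgfra.

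Coordinates are those of GENCODE vM21 on GRCm38, the assembly also called mm10, and 22197 of the 23238 symbols matched a gene there. Genes that overlap an antisense gene cannot be told apart from it, because the use of strand is not stated.

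The alternatives fixed beforehand were other scalings, other tests (DESeq2 1.42.0, edgeR's exact test, limma-voom, a robust fit), other filters and thresholds, other set tests, and leaving out each library in turn. Alternatives chosen after seeing the data kept the rows of a symbol apart, left out the ribosomal RNA precursor Rn45s, or used edgeR's newer quasi-likelihood method. After the top genes were seen, 7 further gene lists were tested: circadian clock, osmotic response, class I histocompatibility, acute phase, YAP and serum response factor targets, non-polyadenylated RNAs and replication-dependent histones. A scan along the chromosomes for neighbouring genes that moved together was also added then. It looked for windows of 5 neighbouring tested genes of which 4 or more were at least 2-fold above the mean log2 level of the other 3 libraries, with 0.5 CPM added, and it was repeated on the difference between the group means. Its null was 1000 shuffled gene orders. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

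The steps were tested on simulated counts for the same 16270 genes, 4 libraries and spread, with 200 genes changed. The quasi-likelihood test recovered 64% of genes changed by 1 on the log2 scale and 100% of those changed by 2, with 15 false calls. Camera called 0 of 36 lists with no change, and called the NRF2 list, with no other, when its members were shifted by 0.5. The simulated genes were drawn independently of each other, whereas the correlation estimated within lists of the real data reached 0.51 (ribosomal proteins). It was nearer the preset value for NRF2 (0.026), hypoxia (0.028) and glycolysis (-0.011). This simulation therefore cannot show how often camera with its preset correlation calls lists falsely here.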

Results

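The data set compared cultured mouse cavernous endothelial cells in normal and high glucose after 72 hours, with 2 libraries per group. Its title states the purpose as a profile of transcription under both conditions. Totals ran from 46571770 counts in normal glucose replicate 2 to 74971589 in high glucose replicate 4, and 18190 to 18801 genes had at least 1 count. Normal glucose replicate 2 stood apart: its log2 CPM had a Pearson correlation across genes of 0.978 with its own group's other library, against 0.988 between the high glucose libraries. Normal glucose replicate 1 was closer to the high glucose libraries (0.985 and 0.987) than to its own group's replicate 2, so the libraries did not group by glucose. Genes are not independent replicates, so these correlations describe the libraries only.

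In all 4 libraries the transcripts typical of endothelium were scarce and those typical of connective tissue were abundant. The endothelial adhesion molecule Pecam1 (chromosome 11, 106654217 to 106750628) had 3.51 ± 0.0965 CPM in normal and 2.56 ± 0.336 CPM in high glucose. The endothelial cadherin Cdh5 had 5.58 ± 1.38 and 4.92 ± 0.251 CPM, the receptor Kdr 1.02 ± 0.0228 and 1.33 ± 0.106 CPM, Vwf 0.833 ± 0.0225 and 0.753 ± 0.134 CPM, and Nos3, the endothelial nitric oxide synthase, 0.642 ± 0.0322 and 0.702 ± 0.083 CPM. None of these 5 genes was called between the groups (unadjusted p from 0.12 to 0.76, edgeR), though Pecam1 was lower in both high glucose libraries. Cd34 (758 ± 11.6 and 812 ± 95.6 CPM) and Eng (166 ± 57.7 and 138 ± 6.16 CPM) were the abundant members of the endothelial list, but fibroblasts can express both. The fibroblast markers Dcn (5394 ± 458 and 6530 ± 1510 CPM), Col1a1 (2376 ± 799 and 1607 ± 555 CPM), Prrx1 (916 ± 150 and 981 ± 29.1 CPM) and Pdgfra (310 ± 68.8 and 365 ± 3.48 CPM) were far higher. Of 26 endothelial identity genes, 13 had a mean under 1 CPM, while none of 16 fibroblast markers did. The median endothelial identity gene lay between 0.908 and 1.27 CPM, and the median fibroblast marker between 161 and 229 CPM. Camera called neither the endothelial identity list (adjusted p = 0.0886) nor the fibroblast list (adjusted p = 0.971). The endothelial list had a median log2 fold change of -0.18, with 15 of 23 tested members below 0 and 8 above. Its lowest p belonged to Flt1 (22.3 ± 2.94 and 14.1 ± 0.615 CPM, unadjusted p = 0.0107, edgeR), so a modest fall is not excluded.

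**Figure D1:**
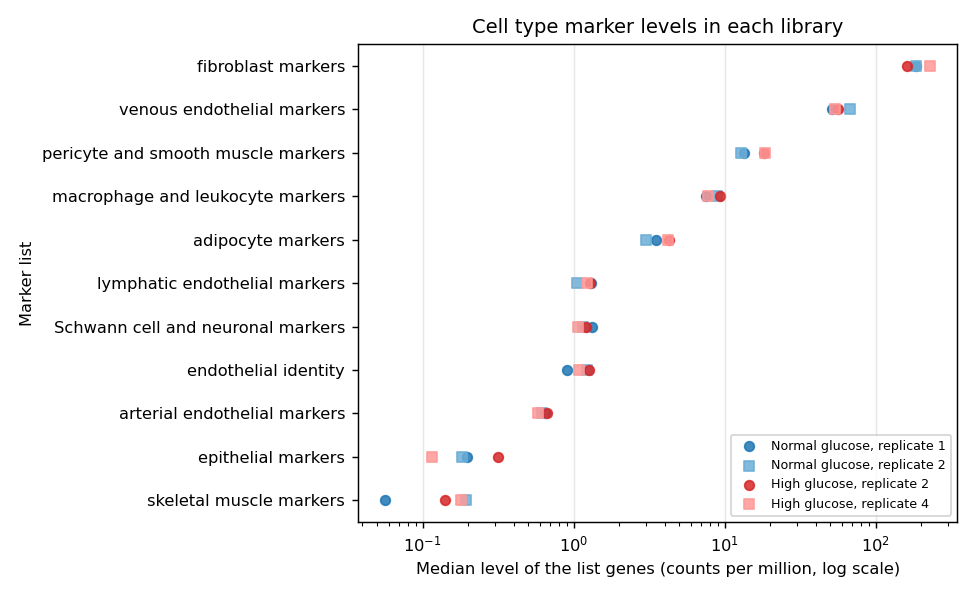
Median CPM (log scale) of each list of cell type markers, with a point for each of the 4 libraries. The fibroblast list is highest in every library, at 161 to 229 CPM, and the endothelial identity list lies near 1 CPM.

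Two-sided testing of high against normal glucose found 2 genes past the threshold, and both rose. H2-Q10, a class I histocompatibility gene (chromosome 17, 35470089 to 35474563), rose from 12.6 ± 0.635 to 110 ± 1.91 CPM, a log2 fold change of 3.12 (SE 0.19, adjusted p = 0.00179, edgeR). Hist1h4d, a histone H4 gene (chromosome 13, 23581598 to 23582735), rose from 0.417 ± 0.266 to 10.6 ± 1.04 CPM, a log2 fold change of 4.59 (SE 0.40, adjusted p = 0.0163). Both genes were higher in each high glucose library than in each normal glucose library. By itself this was common: 5294 of the 16270 genes tested had no overlap between the groups, in either direction. H2-Q10 shares 29.1% of its 32-base stretches with related genes, and Hist1h4d shares 14.5%, so their counts could include reads of relatives. No gene fell past the threshold, while at an unadjusted p under 0.05 there were 361 higher and 526 lower genes, against 813.5 expected by chance. DESeq2 called 36 risen and 38 fallen genes, edgeR's exact test 56 and 56, and limma-voom 2 and 0. Without normal glucose replicate 1 the count was 2667, without normal glucose replicate 2 it was 157, and without high glucose replicates 2 or 4 it was 32 or 36.

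Hist1h4d lies among other histone genes that were also higher in both high glucose libraries, none past the threshold. Hist1h2ac had 2.66 ± 0.482 CPM in normal and 12.4 ± 0.894 CPM in high glucose (adjusted p = 0.0672, edgeR), and Hist1h2be had 16.4 ± 3.05 and 48.6 ± 0.745 CPM (adjusted p = 0.158). Further along the chromosome, Hist1h1b had 19.2 CPM in normal glucose replicate 1 and 0.665, 0.973 and 0.671 CPM in the other 3 libraries. These genes were chosen after their values were seen.

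**Figure D2:**
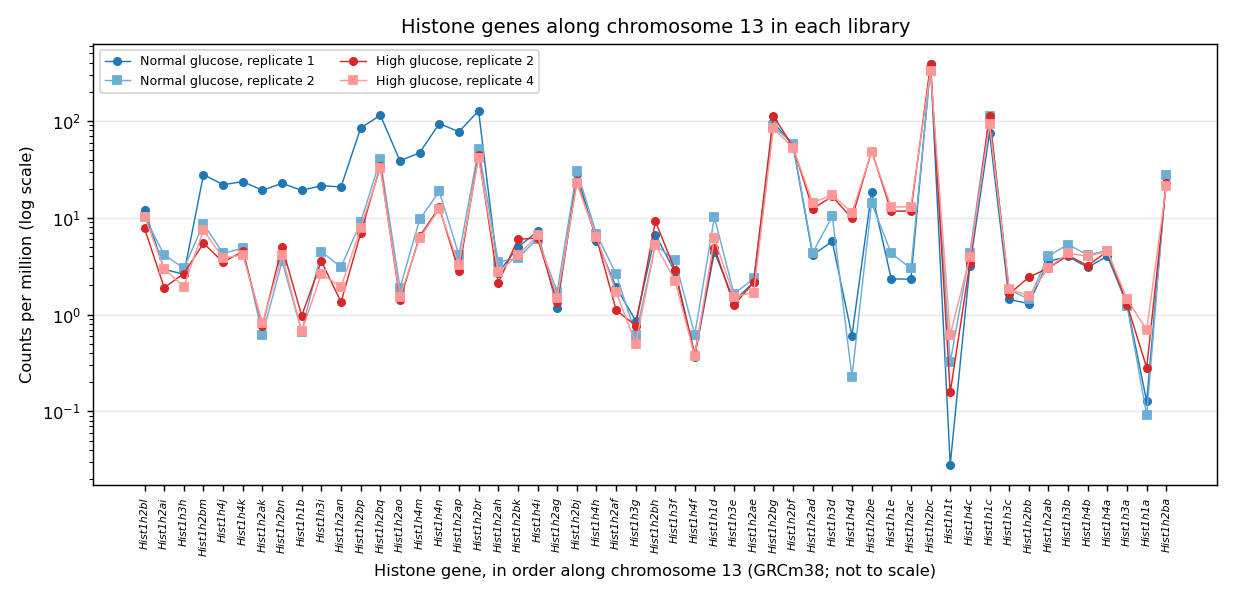
CPM (log scale) of 53 histone genes of chromosome 13, in genomic order, with 1 line per library. Normal glucose replicate 1 lies above the other 3 libraries over the 15 genes from Hist1h2bm to Hist1h2br, and both high glucose libraries lie above both normal glucose libraries over the 6 genes from Hist1h2ad to Hist1h2ac.

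Camera called the list of NRF2 antioxidant genes higher in high glucose, with a median log2 fold change of 0.42 (adjusted p = 9.2e-12), but not with an estimated correlation (adjusted p = 0.509). Slc7a11, which imports cystine for glutathione synthesis (chromosome 3, 49892526 to 50443614), had 127 ± 8.44 CPM in normal and 278 ± 17.8 CPM in high glucose, a log2 fold change of 1.13 (SE 0.18). Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis (chromosome 9, 77754535 to 77794485), had 182 ± 1.38 and 370 ± 12.5 CPM, and the quinone reductase Nqo1 (chromosome 8, 107388225 to 107403206) had 152 ± 20.9 and 322 ± 35.8 CPM. Over all genes tested, 0 of the 22 members passed (adjusted p of these 3 from 0.345 to 0.397, edgeR). Adjusted over the list alone, 8 rose and 0 fell: Slc7a11, Gclc, Nqo1, Sod2, Gsta4, Prdx1, Gclm and Srxn1. Sod2 shares 21.8% of its 32-base stretches with another gene. Hmox1, another NRF2 target, had 4114 ± 1033 and 3855 ± 746 CPM, and Me1 had 144 ± 16.8 and 140 ± 17.4 CPM. The list of polyol, pentose phosphate and hexosamine pathways, the side routes of glucose metabolism, had a median of 0.21, with 15 of 17 members above 0 (camera adjusted p = 8.9e-04, adjusted p = 0.537 with an estimated correlation). Without normal glucose replicate 2 its adjusted p was 0.0773. None of its members passed over all genes or adjusted over the list alone. Its lowest p belonged to the aldose reductase Akr1b3, which shares 10.2% of its 32-base stretches with other genes, with 14.6 ± 3.22 and 26.8 ± 0.22 CPM.

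Camera called hypoxia-induced and glycolytic genes lower with its preset correlation only. The hypoxia list outside glycolysis had a median log2 fold change of -0.36 over 20 members (camera adjusted p = 5.5e-07, adjusted p = 0.509 with an estimated correlation). None passed over all genes tested, and 4 fell and 0 rose adjusted over the list alone. Those were Mxi1 (96.9 ± 13 and 57 ± 0.314 CPM), Ero1l (2171 ± 217 and 1390 ± 58.1 CPM), the HIF prolyl hydroxylase Egln3 (267 ± 7.34 and 170 ± 17.9 CPM) and Ndrg1 (394 ± 82 and 239 ± 20.4 CPM). Vegfa had 1628 ± 10.7 and 1282 ± 135 CPM, and Hif1a itself 420 ± 75.6 and 549 ± 14.5 CPM. The list of glycolysis and glucose transport had a median of -0.30, with 18 of 21 members below 0 (camera adjusted p = 1.2e-04, adjusted p = 0.509 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Its median was -0.20 without normal glucose replicate 2 and -0.20 without high glucose replicate 4, and -0.21 without normal glucose replicate 1. Slc2a1, the glucose transporter GLUT1 (chromosome 4, 119108711 to 119137983), had 2652 ± 715 and 1573 ± 70.6 CPM (log2 fold change -0.75, SE 0.22), and Aldoc, an aldolase, 32.9 ± 6.1 and 17.6 ± 1.7 CPM. The lactate transporter Slc16a1 went the other way, with 175 ± 36 and 243 ± 13.8 CPM. The list of MondoA and ChREBP targets, which respond to glucose in many cells, was not called (camera adjusted p = 0.526). Its member Txnip (chromosome 3, 96557957 to 96561883) had 524 ± 5.62 CPM in normal and 437 ± 20.4 CPM in high glucose (unadjusted p = 0.17).

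**Figure D3:**
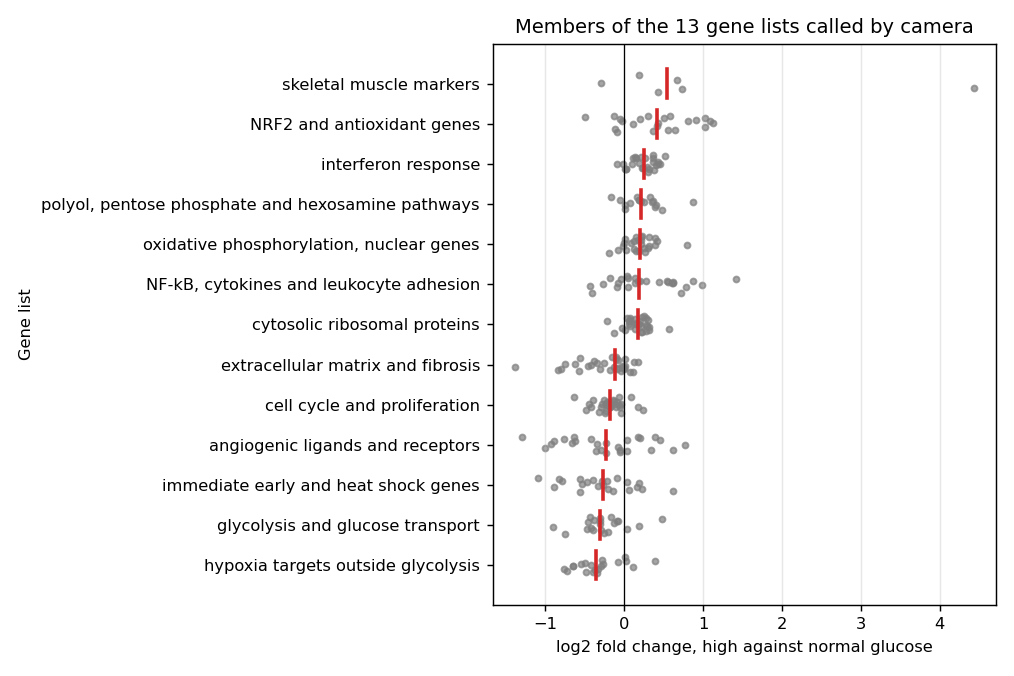
Log2 fold changes of the members of the 13 gene lists called by camera, with a point per gene and a red bar at the list median. List medians run from -0.36 for the hypoxia list to 0.55 for the skeletal muscle list.

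Camera called the list of NF-kB, cytokine and leukocyte adhesion genes higher, with a median of 0.19 (adjusted p = 2.5e-06), but not with an estimated correlation (adjusted p = 0.537) or without normal glucose replicate 1 (0.178). It called interferon response genes higher, with a median of 0.25 (adjusted p = 1.2e-04), but not with an estimated correlation (adjusted p = 0.537) or without normal glucose replicate 2 (0.1002). Il6 (chromosome 5, 30013114 to 30019981) had 14.9 ± 0.436 CPM in normal and 39.7 ± 1.9 CPM in high glucose, a log2 fold change of 1.41 (SE 0.19, adjusted p = 0.158, edgeR). In the NF-kB list, 0 of 26 members passed over all genes, and Il6 and the chemokine Cxcl1 (106 ± 13.3 and 193 ± 9.28 CPM) were the 2 that rose adjusted over the list alone. The adhesion molecule Vcam1 had 345 ± 40.6 and 524 ± 38.7 CPM, while Tnf had 1.47 ± 0.262 and 1.21 ± 0.108 CPM and Nfkbia 181 ± 38.3 and 185 ± 16.1 CPM. Of 26 interferon response genes, 24 lay above 0. None passed over all genes or adjusted over the list alone.

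Camera called the list of extracellular matrix and fibrosis genes lower, with a median of -0.12 (adjusted p = 6.9e-05), but not with an estimated correlation (adjusted p = 0.537). It called angiogenic ligands and receptors lower, with a median of -0.24 and 9 of 26 members above 0 (adjusted p = 0.0051), but not with an estimated correlation (adjusted p = 0.537), without normal glucose replicate 2 (0.0702) or without high glucose replicate 2 (0.0522). In the matrix list, 0 of 32 members passed over all genes, and 5 fell and 0 rose adjusted over the list alone. Among them were Ctgf (514 ± 204 and 198 ± 2.35 CPM), the collagen cross-linking enzymes Loxl2 (398 ± 10.3 and 236 ± 23 CPM) and Lox (2278 ± 638 and 1306 ± 106 CPM), and Thbs1 (5846 ± 61.2 and 3800 ± 98.8 CPM). The fibrillar collagen Col3a1 had 197 ± 39.1 and 198 ± 49.1 CPM. Among 26 angiogenic ligands and receptors, 0 passed over all genes, and adjusted over the list alone 6 fell (Apln, Cyr61, Thbs1, Cxcl12, Angptl4 and Flt1) and 1 rose, the growth factor Hgf (37.7 ± 0.193 and 58.1 ± 5.81 CPM). Thbs1, which inhibits angiogenesis, is in both lists. Apln, the peptide apelin (chromosome X, 48025146 to 48034853), had 165 ± 30.3 and 82.5 ± 5.95 CPM, a log2 fold change of -1.0 (SE 0.20).

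Among 23 genes of nitric oxide and cGMP signalling, which drives erection, 0 passed over all genes, and adjusted over the list alone 1 rose and 1 fell. Arg2, an arginase that competes with nitric oxide synthase for arginine (chromosome 12, 79130777 to 79156301), had 8.98 ± 1.03 and 19.5 ± 2.26 CPM, a log2 fold change of 1.12 (SE 0.21). It overlaps the antisense gene Vti1b. Ddah1, which breaks down the synthase inhibitor dimethylarginine (chromosome 3, 145758675 to 145894277), had 87.9 ± 15 and 43.9 ± 5.8 CPM, a log2 fold change of -1.0 (SE 0.20). The list as a whole was not called (camera adjusted p = 0.971). The endothelial synthase Nos3 itself had only 0.642 ± 0.0322 and 0.702 ± 0.083 CPM. The levels of Arg2 and Ddah1 therefore do not show a change in endothelial nitric oxide production, which was not measured.

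Camera called 5 further lists. Immediate early and heat shock genes had a median of -0.27 (adjusted p = 0.0051, adjusted p = 0.537 with an estimated correlation, 0.970 without normal glucose replicate 2), with Egr3 at 16.6 ± 7.49 and 8.94 ± 0.704 CPM and Hsph1 at 104 ± 25.6 and 159 ± 1.86 CPM. Cell cycle genes had a median of -0.18, with 29 of 32 below 0 (adjusted p = 0.0099, adjusted p = 0.537 with an estimated correlation), and an adjusted p of 0.223 without normal glucose replicate 1 and 0.0658 without high glucose replicate 4. Ccnd1, cyclin D1, had 324 ± 9.37 and 237 ± 4.3 CPM. Oxidative phosphorylation genes (median 0.20, adjusted p = 0.0059, adjusted p = 0.655 with an estimated correlation) and cytosolic ribosomal protein genes (median 0.18, adjusted p = 0.0094, adjusted p = 0.674 with an estimated correlation) were called higher with all 4 libraries. Without normal glucose replicate 2 both turned downward, with adjusted p of 0.662 and 0.184. In that library Rps3 had 43.5 CPM, against 111 to 132 CPM in the other 3. None of the members of these 4 lists passed over all genes or adjusted over the list alone. Of 6 tested skeletal muscle markers, 1 rose adjusted over the list alone and 0 over all genes: Myh1, with 2 and 0 counts in normal and 12 and 48 counts in high glucose, which shares 37.0% of its 32-base stretches with other myosin genes (median of the list 0.55, adjusted p = 0.0215, adjusted p = 0.537 with an estimated correlation). Its adjusted p was 0.361 and 0.0773 without normal glucose replicates 1 or 2, and 0.0658 without high glucose replicate 4.

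The other lists, in addition to those above, were not called by camera. Adjusted p-values were 0.0868 for adipocyte markers, 0.135 for advanced glycation and scavenger receptors, 0.135 for Schwann cell and neuronal markers, 0.136 for endothelial-to-mesenchymal transition factors, 0.209 for Notch and tip-stalk genes and 0.209 for NADPH oxidase genes. They were 0.211 for junction genes, 0.211 for fatty acid oxidation, 0.247 for arterial, 0.408 for venous and 0.750 for lymphatic endothelial markers, 0.247 for macrophage and leukocyte markers, 0.269 for epithelial markers and 0.294 for pericyte and smooth muscle markers. They were 0.368 for the glycocalyx, 0.750 for sterol synthesis, 0.946 for the unfolded protein response and ATF4 targets, and 0.971 for both insulin signalling and the p53 response. Median, mean and test differed in sign for 5 lists: sterol synthesis (median -0.01, mean 0.01, test up), the unfolded protein response (0.01, -0.02, up), nitric oxide signalling (-0.05, 0.05, down), fibroblast markers (0.05, -0.01, up) and insulin signalling (-0.04, 0.00, up). Adjusted over these lists alone, S100a8 (40.9 ± 17.3 and 95.3 ± 7.44 CPM), Olr1, an oxidised lipoprotein receptor (18 ± 2.27 and 30.5 ± 0.813 CPM), and Cd14 (225 ± 5.44 and 431 ± 11.9 CPM) rose, and Slc7a11 rose in the ATF4 list too. Krt19, Apln and the neuronal genes Tubb3 (17.1 ± 3.36 and 9.3 ± 0.014 CPM) and Ncam1 (89.4 ± 6.25 and 58.2 ± 1.91 CPM) fell, and over all genes tested 0 of these passed.

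Of the other genes the naming rule took by their small p, none passed over all genes tested (adjusted p from 0.285 to 0.440, edgeR). The rule itself required that their groups not overlap. Higher in both high glucose libraries were Dgat1, an enzyme of triglyceride synthesis (53.1 ± 1.14 and 118 ± 1.27 CPM), the aldehyde dehydrogenase Aldh3a1 (28 ± 1.18 and 52.5 ± 2.97 CPM), the serum amyloid gene Saa4 (4.4 ± 0.785 and 9.66 ± 0.537 CPM) and the aminopeptidase Enpep (31.1 ± 2.98 and 57 ± 1.43 CPM). Lower in both were the keratin gene Krt19 (12.4 ± 0.541 and 4.71 ± 0.0486 CPM), Proser2 (10.7 ± 0.679 and 4.48 ± 0.00971 CPM), the clock repressor Ciart (15.2 ± 4.03 and 5.71 ± 0.25 CPM) and Slc27a3 (11.2 ± 2.16 and 3.98 ± 0.93 CPM). Syt5 (8.14 ± 1.85 and 3.17 ± 0.178 CPM), Lbh (70.6 ± 11 and 35.1 ± 2.47 CPM), Kbtbd11 (11.2 ± 0.442 and 5.37 ± 0.248 CPM) and Fam57a (23.5 ± 4.74 and 10.8 ± 1.33 CPM), which overlaps antisense genes, were lower too.

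**Figure D4:**
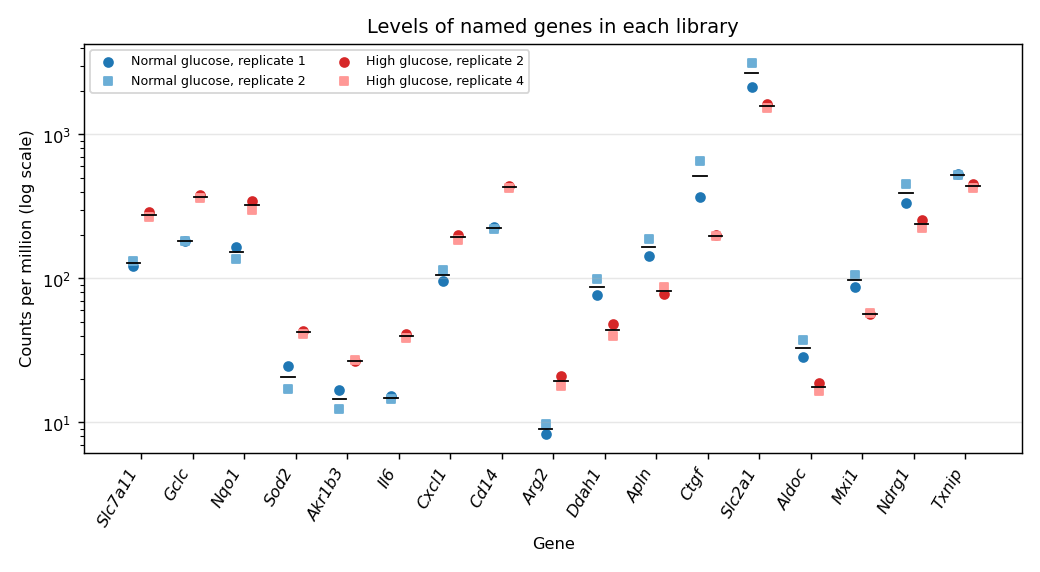
CPM (log scale) of 17 named genes in each library, with normal glucose in blue, high glucose in red and a black bar at each group's mean. Il6 has 14.6 to 15.2 CPM in normal and 38.3 to 41.0 CPM in high glucose, and Slc2a1 has 2147 to 3158 CPM in normal and 1523 to 1623 CPM in high glucose.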

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

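No paired analysis was possible because the groups share only replicate number 2. Alternatives planned for normalized or log2 values did not apply, since the files hold counts. H2-Q10 and Hist1h4d kept their calls under every alternative that was run. The count of called genes was 2 or 3 with the other scalings, limma-voom, the robust fit, limits of 1 or 5 CPM, an adjusted p of 0.10, a fold limit, and the 3 alternatives chosen after seeing the data. It was 74 with DESeq2 (36 risen, 38 fallen), 112 with the exact test (56 and 56), 127 with no filter (62 and 65) and 887 at an unadjusted p under 0.05. Leaving out a library gave 32 to 2667 genes, the highest without normal glucose replicate 1. A group left with 1 library was then assumed to vary like the other group. The cause of these differences was not tested.

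Of 13 lists called, 13 were called with each other scaling, with symbol rows kept apart and without Rn45s, and 12 with no filter (skeletal muscle markers lost, adjusted p = 0.176). With members of at least 5 CPM 13 lists were called, and with at least 1 CPM 14. Skeletal muscle markers, with a highest mean of 1.92 CPM, had too few members to be tested at either limit. Those 13 and 14 therefore include lists not called in the main fit. With an estimated correlation 0 were called: adjusted p was 0.509 for NRF2, hypoxia and glycolysis, 0.655 for oxidative phosphorylation, 0.674 for ribosomal proteins and 0.537 for the other 8. The estimate was -0.011 for glycolysis and -0.029 for the cell cycle, below the preset 0.01. Their unadjusted camera p still rose, from 1.8e-05 to 0.042 and from 0.0033 to 0.078. It was 0.32 for NF-kB, 0.30 for interferon, 0.45 for oxidative phosphorylation and 0.51 for ribosomal proteins. The 0 calls therefore do not show that correlation produced the calls, nor that the lists changed. Fry called 0, with adjusted p of 0.125 for NRF2, hypoxia and the cell cycle, 0.148 for glycolysis, 0.263 for skeletal muscle, 0.388 for angiogenic genes, 0.401 for polyol pathways, 0.407 for NF-kB, interferon and matrix, 0.646 for immediate early genes, 0.685 for oxidative phosphorylation and 0.695 for ribosomal proteins.

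Leaving out a library gave 7 to 12 called lists, the fewest without normal glucose replicate 2. NRF2 (adjusted p from 4.6e-14 to 3.8e-05), hypoxia (3.0e-09 to 0.0082), matrix (1.8e-05 to 0.0406) and glycolysis (1.6e-04 to 0.0230) kept their calls and directions without each library. Ranges for the lists that did not were 4.6e-14 to 0.178 for NF-kB, 3.2e-05 to 0.1002 for interferon, 8.4e-04 to 0.0773 for polyol pathways, 0.0078 to 0.0702 for angiogenic genes, 3.4e-06 to 0.970 for immediate early genes, 0.0050 to 0.223 for the cell cycle and 0.0021 to 0.361 for skeletal muscle. Ribosomal proteins ranged from 3.6e-09 to 0.184 and oxidative phosphorylation from 3.9e-07 to 0.662, and both reversed without normal glucose replicate 2 (0.184 and 0.662). The cause was not tested. In simulated data with 200 changed genes, 64% of those with a log2 change of 1 were found. This sets no limit of detection here, where so few genes were called: Hist1h2ac, with a log2 fold change of 2.23, had an adjusted p of 0.0672 (edgeR).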

Other observations

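Lists chosen after the top genes were seen pointed to further gene groups, so their p-values are not independent evidence. All 4 tested serum amyloid genes, neighbours on chromosome 7 (46711998 to 46754313) that were raised together like the histone block below, rose adjusted over their list alone: Saa1 (8.37 ± 0.747 and 19 ± 1.32 CPM), Saa2 (1.91 ± 0.0705 and 4.58 ± 0.156 CPM), Saa3 (922 ± 455 and 1891 ± 397 CPM) and Saa4. Their acute phase list had a median log2 fold change of 0.50 (camera adjusted p = 2.3e-09, adjusted p = 0.0833 with an estimated correlation), and Saa1 and Saa2 share over 40% of their 32-base stretches. YAP and serum response factor targets had a median of -0.36, with 18 of 19 members below 0 (camera adjusted p = 3.7e-08, adjusted p = 0.130 with an estimated correlation), and Ctgf and Cyr61 (544 ± 120 and 293 ± 10.7 CPM) fell adjusted over the list alone. Class I histocompatibility genes had a median of 0.13 (camera adjusted p = 1.4e-08, adjusted p = 0.0833 with an estimated correlation), with H2-Q6 at 9.59 ± 1.03 and 20.8 ± 3.35 CPM beside H2-Q10. Circadian clock genes had a median of -0.15 (camera adjusted p = 0.0022, adjusted p = 0.284 with an estimated correlation), with 13 of 17 members below 0, and Ciart and Bhlhe40 fell adjusted over the list alone (Bhlhe40 205 ± 29.2 and 125 ± 5.06 CPM). Osmotic response genes had a median of 0.20 (camera adjusted p = 3.6e-04, adjusted p = 0.130 with an estimated correlation), and the aldose reductase Akr1b3 and the betaine transporter Slc6a12 (1.3 ± 0.054 and 2.68 ± 0.0303 CPM) rose adjusted over the list alone. The list of 5 non-polyadenylated RNAs had a median of 0.24 (camera adjusted p = 0.315, adjusted p = 0.435 with an estimated correlation), and 64 replication-dependent histone genes a median of -0.21 (camera adjusted p = 0.447, adjusted p = 0.435 with an estimated correlation).

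Of the tests below, those on marker levels, on reads shared among histone genes, on replicating cells and on gene order, and the bound that decides the one on non-polyadenylated RNA, were chosen only after the results were seen. The H2-Q10 test met its preset bound but was then left open, because a sum over relatives lets the rise of some hide a fall in another. The limit of the test on reads shared among histone genes also went from 0.1 to 0.5 of the block's gain. With 0.1 and the rest unchanged, that test would have been left open. The test on time of day, set beforehand, was left open because its genes went both ways.

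Histone genes moved in blocks of neighbours that differed between libraries. In normal glucose replicate 1, all 15 tested genes from Hist1h2bm to Hist1h2br (chromosome 13, 21722044 to 21837530) were at least 2-fold above the other 3 libraries, with a median of 27.96 CPM against 4.09 to 4.49 CPM. Against the other 3 libraries, high glucose replicate 2 was raised over 4 genes from Hist1h4d to Hist1h2ac, and replicate 4 over 5 of 6 from Hist1h2ad to Hist1h2ac. Between the group means all 6 were raised (23574381 to 23683948, medians 12.1 and 13.7 against 3.24 and 4.32 CPM). High glucose replicate 4 alone was raised over Trim38 and 4 Slc17a genes (23769913 to 23915009), with Slc17a1 at 7.54 CPM, 0.688 CPM in normal glucose replicate 2 and no count in the other 2 libraries, where a floor of 3 counts is 0.0422 and 0.0471 CPM. High glucose replicate 2 was raised over 6 of 7 genes from Cyp2d11 to Cyp2d40 on chromosome 15 (median 1.44 CPM), which were also raised between the group means (0.464 CPM in replicate 4, 0 and 0.0459 CPM in normal glucose), and normal glucose replicate 2 over 6 of 8 genes from Sprr1a to Lce3d on chromosome 3. The group means also differed over the 4 genes from Saa3 to Saa2, and over the 5 genes from Trim38 to Slc17a4. The latter difference came from high glucose replicate 4, with a median of 6.04 CPM against 0 CPM in high glucose replicate 2.

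Chance order gave as many such windows in 0 of 1000 shuffles in any library, which argues against neighbours moving together by chance, though neighbouring relatives can also share regulation. Reads moved from other histone genes into the block of normal glucose replicate 1 would lower those genes. The 43 histone genes outside the blocks summed to 22.4 CPM more in that library than in the other 3 libraries (SD 49.8). Its block gained 618 CPM, so these sums argue against a share of 0.5 or more of that gain having moved from those 43 genes. A share near the earlier limit of 0.1 stays open. The sums do not test reads counted for several copies, which need not lower any gene. Hist2h3c1 and Hist2h3c2 had equal CPM in each library (36.1 and 60.7 in normal, 32.9 and 34.3 in high glucose). Genes of the block shared 2.81% to 98.2% of their sequence stretches with other genes. Reads counted more than once within the block therefore stay open. More replicating cells in high glucose would raise the cell cycle list, whose median was -0.1844 (spread 0.025) and at most -0.1343 without any 1 library. More capture of non-polyadenylated RNA would need a median of at least 0.5 of the 1.78 in the histone block. The 5 such RNAs had 0.2403 (spread 0.0219), from -0.33 for Snord118 to 0.31 for Rn45s, with SE from 0.20 to 0.47. Each spread, here and below, is a scaled median absolute deviation over the square root of the number of genes. It leaves out the difference between libraries: Rn45s had 28535 and 17309 CPM in high glucose replicates 2 and 4. The cell cycle test and this one are therefore less sharp than their spreads. For H2-Q10, which rose by 97.0 CPM, the 17 genes most like it summed to 3250 ± 202 CPM in normal and 4162 ± 1192 CPM in high glucose. That is 912 CPM higher (SE 855), but not in both high glucose libraries alike. In replicate 4, H2-Q1 and H2-Q2 had 770 and 601 CPM. They had 149 and 117 CPM in high glucose replicate 2, and at most 196 and 92.6 CPM in normal glucose. Shared reads stay open, since H2-K1 among the 17 was lower in both high glucose libraries by more than the rise of H2-Q10 (1226 ± 60.6 and 1070 ± 0.61 CPM). A candidate explanation, not tested because it needs the reads, is transcription running through neighbouring genes from a start site that differs between cultures. Some blocks sit in 1 library only and others in both high glucose libraries, so whether the block with Hist1h4d marks the cultures or the glucose may not be settled here.

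The scarcity of endothelial transcripts was not a matter of depth: in the shallowest library the median endothelial identity gene still had 53.5 counts. The median fibroblast marker was 127 to 210 times the median endothelial identity gene in the 4 libraries. Cultures in which connective tissue cells make up a large part could give this, and Dcn, Col1a1 and Prrx1 were among the abundant transcripts. Pericyte and smooth muscle markers were present too, with a median of 15.7 CPM and 9 of 16 over 10 CPM. The venous endothelial list had a median of 57.2 CPM. Of the 26 endothelial identity genes, 5 were over 10 CPM (Cd34, Eng, Esam, Sox7 and Flt1). These levels do not name a single other cell type. Endothelial cells that lost their identity in culture cannot be told apart from such mixed cultures, because no library of known composition was among the 4. The difference concerns all 4 libraries alike, and the design gives no group to test a biological explanation.

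The NRF2 list was higher while the hypoxia and glycolysis lists were lower. Random lists matched on expression, GC content and transcript length were as far from 0 as the NRF2 list in 1 of 10000 draws. They were as far as the other 2 lists in 0 draws, which argues against those gene properties as the whole account of these 3 lists. The middle 95% of lists matched to glycolysis lay mostly below 0 (-0.18 to 0.04, against its mean of -0.27). Lists matched to the matrix list lay below 0 too (-0.18 to -0.01, against its mean of -0.22). Part of these 2 falls may go with those properties. Of the other 10 called lists, only the ribosomal protein mean of 0.16 lay inside the middle 95% of its matched lists (-0.11 to 0.17, 262 as far), and oxidative phosphorylation was reached by 216, angiogenic genes by 123 and skeletal muscle markers by 60. No library decided the pattern: without any 1 of the 4, each list median kept its sign and at least 0.65 of its size. A different time of day at harvest stays open. The Per, Dbp, Nr1d and Tef genes had a median of -0.0624 (spread 0.14) but went both ways, from Per2 at -0.38 to Nr1d2 at 0.39. The opposing arm of the preset test had a median of -0.34, with Npas2 (-0.64) and Arntl (-0.34) lower and Clock (0.03) not. Outside both arms, Ciart (-1.41), Bhlhe41 (-0.76) and Bhlhe40 (-0.72) were lower. Higher osmolarity stays open too, since osmotic response genes had a median of 0.20 (spread 0.14) and no osmotic control was among these libraries, so an effect of glucose itself may be proposed only as a hypothesis.

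At an unadjusted p under 0.05 the real grouping gave 887 genes and the higher of the other 2 splits gave 571, so 1 of 3 splits gave as many. With 3 splits the share cannot be under 0.05.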
